A study of Caenorhabditis elegans with 16 samples.

How the data were processed

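Transcript abundance was measured by RNA sequencing of total RNA from whole *C. elegans* animals, extracted with a Zymo Direct-zol kit, per the labels' protocols. Animals grew for 48 h to the L4 stage and were then exposed for 4 h to OP50 or PA14, per the labels' protocols. The deposited table held raw counts of reads per gene for the 16 libraries, as whole numbers, with 1 column per library. Per the submitters' processing notes, the tools used upstream were CASAVA 1.8, TopHat2 2.0.12 with Bowtie2 2.2.3, HTSeq 0.6.1 and DESeq2 1.18.0, and the genome build was ce11. Which of these steps removed reads that map to several places, and whether the counting used strand, is not given in the sources used here. Genes with near-identical copies (vitellogenins, collagens, major sperm proteins and nematode-specific peptide genes) and genes with exons overlapping another gene, such as gst-4, acdh-2 and tph-1, therefore have uncertain separate levels.

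Each library was assigned to its group from its label. The table had 46726 genes, 43623 of which matched a symbol in the reference tables, with 626 symbols shared by several identifiers; these were kept apart by identifier. There were 0 rows naming no gene and 0 columns with per-sample values that were not used. Coordinates came from the Ensembl release 115 annotation of the same assembly, counted from 1. The total counts per library lay between 19160000 and 26570000.

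Genes were kept with the filter of edgeR 4.0.16 (filterByExpr, minimum count 10), which left 15562 genes, and libraries were scaled by TMM. One quasi-likelihood model in edgeR was fitted over all 16 libraries with a term per group, so the groups shared 1 estimate of the spread. It tested 4 comparisons of 2 groups and the difference of the PA14 effects, each adjusted by the Benjamini-Hochberg method over all genes with a threshold of 0.05. Every adjusted p given for a gene comes from this test unless another is named. Log2 fold changes used the edgeR prior count of 0.125, and levels are TMM-normalized counts scaled by library size (CPM), with the SD over 4 libraries. The SE of a log2 fold change was its size divided by the square root of the F value of the test. The 95% intervals are normal intervals from this SE. With few counts in a group this SE can be too small, so it is only approximate there. The analysis ran in R 4.3.3 with version 1.17.8 of the data.table package.

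Before the data were examined, 41 gene lists were fixed, all of which had at least 5 tested members. Each was tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, and again with the correlation estimated per list; p-values were adjusted over the 41 lists of each comparison. The number of lists past the threshold was 25 for PA14 in wild type, 20 for PA14 in skn-1gf, 17 for skn-1gf on OP50, 20 for skn-1gf on PA14 and 18 for the difference of effects. With the estimated correlation these numbers were 10, 6, 2, 0 and 5.

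The genes named were also set by a rule fixed before the data were examined. It took 11 genes tied to SKN-1, serotonin and infection in every comparison. To these it added, for each comparison of 2 groups, the 6 highest and 6 lowest log2 fold changes among genes with a gene name, an adjusted p under 0.05, a mean log2 CPM of at least 2 and no overlap between the libraries of the groups. For the difference of effects it took the 4 highest and 4 lowest without the condition on overlap. From each list described it took up to 4 members with the smallest p, and any member of the serotonin list.

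The scripts were tested on simulated counts for 15562 genes with 200 changed genes per comparison. Of the changes of a log2 of 0.5, 1 and 2, the test recovered 52.7%, 65.8% and 89.9% for PA14 in wild type, 55.4%, 72.3% and 94.1% for PA14 in skn-1gf, 46.7%, 75.8% and 90.0% for skn-1gf on OP50, 41.8%, 71.9% and 95.4% for skn-1gf on PA14, and 30.9%, 54.3% and 82.8% for the difference of effects. False calls made up 6.71%, 7.55%, 5.56%, 3.55% and 3.60% of the calls in these comparisons. In a simulation of PA14 in wild type, 5 of 41 random lists were shifted by a log2 of 0.5, and camera called 5 shifted and 0 unshifted lists. Genes were simulated independently, so this does not test camera on lists whose genes move together.

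The alternatives were scaling by RLE, by the upper quartile and by library size alone, DESeq2 1.42.0, limma voom, no filter and a stricter filter on low counts (CPM of at least 2 in at least 4 libraries), a fit on only the 2 groups compared, the replicate number as a block, a minimum fold change (log2 of 1), only genes with a mean log2 CPM of 3 or more for the correlations, and each library left out in turn. An alternative without both wild-type replicate 2 libraries was chosen after seeing the data. For the shared wild-type OP50 libraries, 20 simulations without effects and 6 splits of the controls were run. No sample was left out of the main analysis. A correction for GC content and gene length was not run, since no genome sequence was used here. Figures were drawn with matplotlib 3.10.9.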

Results

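The series measured transcript abundance by RNA sequencing in whole *Caenorhabditis elegans* at the fourth larval stage (L4). Wild-type animals and animals carrying skn-1gf(lax188), a gain-of-function allele of skn-1, were compared. SKN-1 is the worm ortholog of the Nrf family of transcription factors, which activate detoxification and oxidative stress genes. Animals were raised on *Escherichia coli* OP50, the standard laboratory food, for 48 h and then spent 4 h on OP50 or on PA14, a virulent strain of *Pseudomonas aeruginosa*. The 16 libraries fell into 4 groups of 4: wild type on OP50, wild type on PA14, skn-1gf on OP50 and skn-1gf on PA14. The title of the series names serotonin and the response to the pathogen, so the genes of serotonin synthesis were followed in each comparison. Total counts per library ranged from 21060000 to 25070000 for wild type on OP50, from 20490000 to 25490000 for wild type on PA14, from 19160000 to 26570000 for skn-1gf on OP50 and from 19850000 to 24220000 for skn-1gf on PA14. Of 46726 genes in the table, 15562 passed the filter on low counts and were tested. The labels number the replicates without saying that they came from separate cultures, so p-values measure the spread between these libraries.

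The first principal component of log2 CPM (counts scaled by library size) held 59.9% of the variance and separated the genotypes. The second held 16% and separated the bacteria. Wild-type OP50 replicate 2 lay at 38.7 on the third component, against 5.32 to 9.31 for the other libraries of its group. Transcripts of the mitochondrial genome took 0.538 ± 0.0843% and 0.571 ± 0.0472% of counts in wild type on OP50 and PA14, against 0.963 ± 0.104% and 1.01 ± 0.0633% in skn-1gf (SD, n = 4). The skn-1 gene (WBGene00004804, chromosome IV, 5651039 to 5660384, build ce11) had 143 to 149 CPM in the 4 libraries of wild type on OP50 and 147 to 170 in wild type on PA14. In skn-1gf it had 110 to 140 CPM on OP50 and 119 to 128 on PA14. Its exons overlap a gene on the opposite strand, and whether the counting used strand is not given in the sources used here. A gain-of-function allele need not change its own transcript level, so this level does not check the labels. The SKN-1 target gst-4 (WBGene00001752, chromosome IV, 10142225 to 10143099), a glutathione S-transferase widely used as a SKN-1 reporter, had 28 ± 6.1 and 23.4 ± 4.32 CPM in wild type on OP50 and PA14, against 403 ± 22.9 and 236 ± 13.6 in skn-1gf (SD, n = 4).

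**Figure D1:**
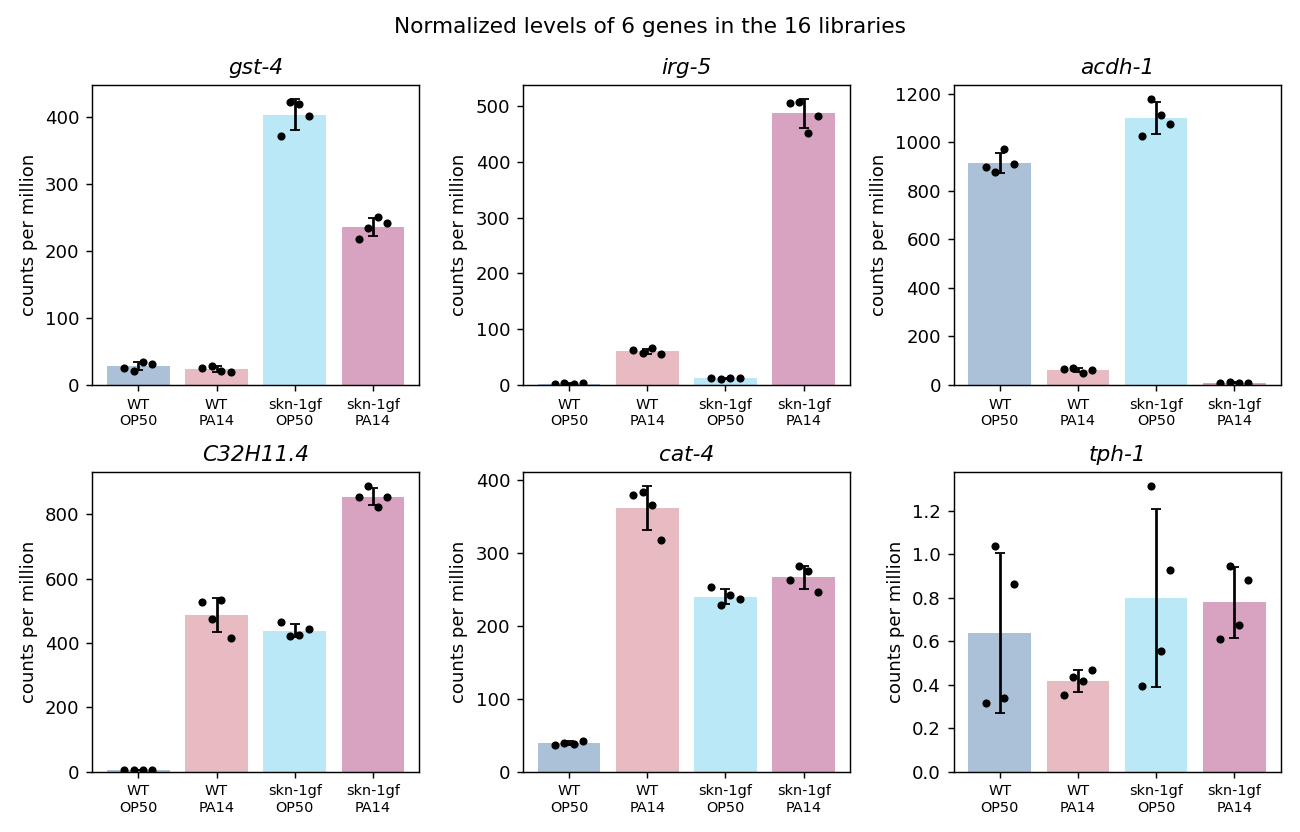
Bars give the mean and error bars the SD of TMM-normalized CPM in each group of 4 libraries, and points give single libraries, for 6 genes on linear axes that start at 0. In gst-4 both skn-1gf groups lie above both wild-type groups, while cat-4 and C32H11.4 are low in wild type on OP50 and higher in the other 3 groups.

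The first comparison asked what 4 h on PA14 changed in wild-type animals. Of 19 p38/PMK-1-associated immune effectors 17 rose, while all 7 propionate shunt genes, 14 of 16 methionine cycle genes and 14 of 24 fatty acid synthesis and desaturation genes fell. The infection response gene irg-6 (WBGene00007864, chromosome IV, 12912722 to 12914969) went from 0.0529 ± 0.106 to 21.5 ± 1.72 CPM, on 5 counts summed over the OP50 libraries. C32H11.4 (WBGene00007867, chromosome IV, 12921264 to 12923296) is a CUB-like domain gene. It went from 6.51 ± 0.501 to 487 ± 54.1 CPM (SD, n = 4). Other genes of the fixed immune lists that rose included dod-24, with a log2 fold change of 4.54 ± 0.065 (SE), irg-5 with 4.62 ± 0.10, irg-4 with 4.14 ± 0.11 and irg-1 with 4.47 ± 0.17. In the opposite direction acdh-1 (WBGene00016943, chromosome I, 6497436 to 6499560), the acyl-CoA dehydrogenase of the propionate shunt, fell from 914 ± 41.1 to 63.1 ± 8.78 CPM. The edgeR quasi-likelihood test called 2589 genes higher and 2027 lower on PA14, of which 965 and 318 changed by at least 2-fold.

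Of 19 tested p38/PMK-1-associated immune effectors, 17 rose and 1 fell, and the counts adjusted over the list alone were also 17 and 1 (camera adjusted p = 2.6e-23, and adjusted p = 3.4e-05 with an estimated correlation). The lysozyme gene lys-2 rose by a log2 of 3.04 ± 0.069 and sysm-1 by 1.47 ± 0.19 (SE). Of 8 genes tied to the transcription factor ZIP-2, 7 rose and none fell (7 and 0 adjusted over the list alone; adjusted p = 6.3e-08, and adjusted p = 0.0014 with an estimated correlation), led by irg-3 at 5.73 ± 0.078. C-type lectins moved both ways, with 43 of 127 higher and 19 lower (46 and 22 adjusted over the list alone; adjusted p = 0.0023, and adjusted p = 0.033 with an estimated correlation). In that family clec-74 reached a log2 fold change of 6.26 ± 0.18 and clec-166 one of -4.14 ± 0.21. SKN-1 phase 2 detoxification targets rose in 15 of 22 cases with none lower (17 and 0 adjusted over the list alone; adjusted p = 6.7e-10, and adjusted p = 0.011 with an estimated correlation). gcs-1, which encodes the rate-limiting enzyme of glutathione synthesis, rose by a log2 of 1.01 ± 0.061, wdr-23, a negative regulator of SKN-1, by 0.78 ± 0.058, and gst-38 by 6.15 ± 0.16. gst-4 had a log2 fold change of -0.27 ± 0.15 (adjusted p = 0.19) and skn-1 one of 0.12 ± 0.061 (adjusted p = 0.14), which did not pass the test. Without wild-type OP50 replicate 2 gst-4 fell by 0.37 (adjusted p = 0.0241). skn-1 passed with upper quartile scaling (0.16, adjusted p = 0.0489) and with library size alone (0.20, adjusted p = 0.0125).

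All 7 propionate shunt genes fell in wild type on PA14 (7 adjusted over the list alone; adjusted p = 2.9e-09, and adjusted p = 0.0015 with an estimated correlation), among them hphd-1 at -1.33 and hach-1 at -0.80. Of 16 methionine and S-adenosylmethionine cycle genes, 14 fell and 1 rose (14 and 1 adjusted over the list alone; adjusted p = 1.1e-13, and adjusted p = 0.0014 with an estimated correlation). They included the nuclear receptor nhr-114 at -3.19, the folate transporter folt-2 at -3.05 and the S-adenosylmethionine synthetase sams-1 at -1.62. Of 24 fatty acid synthesis and desaturation genes, 14 fell and 2 rose (15 and 2 adjusted over the list alone; adjusted p = 4.4e-07, and adjusted p = 0.0014 with an estimated correlation), with elo-2 at -2.58, elo-6 at -2.80 and fat-7 at -3.79. Peroxisomal and mitochondrial beta-oxidation genes split, with 23 of 39 higher and 10 lower (25 and 11 adjusted over the list alone; adjusted p = 5e-05, and adjusted p = 0.0057 with an estimated correlation). There acox-1.5 rose by a log2 of 2.53 and ech-7 fell by 4.14. All 6 vitellogenin genes, which encode egg yolk proteins made in the intestine, fell (6 adjusted over the list alone; adjusted p = 8.1e-08, but adjusted p = 0.071 with an estimated correlation). vit-3, vit-4 and vit-5 are close paralogs whose reads the counting could divide, so their separate values are uncertain. Sperm genes, which mark the male germ cells of hermaphrodites, rose in 58 of 87 cases with none lower (60 and 0 adjusted over the list alone; adjusted p = 4.9e-13, but adjusted p = 0.081 with an estimated correlation).

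Among 14 genes of serotonin synthesis, transport and reception, 4 rose and 2 fell in wild type on PA14, which was not a shift of the list (4 and 2 adjusted over the list alone; adjusted p = 0.29). cat-4 (WBGene00000298, chromosome V, 10564880 to 10566464) encodes the GTP cyclohydrolase that makes the cofactor of aromatic amino acid hydroxylases. It rose from 39.1 ± 2.52 to 362 ± 29.9 CPM (SD, n = 4), a log2 of 3.21 ± 0.067 (SE), and ptps-1, in the same cofactor pathway, rose by 1.45 ± 0.16. tph-1 (WBGene00006600, chromosome II, 7549335 to 7551983), the tryptophan hydroxylase of serotonin neurons, had low counts in whole animals, with 56, 38, 69 and 73 counts summed over the 4 libraries of wild type on OP50 and PA14 and of skn-1gf on OP50 and PA14. Its log2 fold change on PA14 was -0.59 ± 0.52 (adjusted p = 0.43), with a 95% interval from -1.61 to 0.43. Changes within that range were not excluded. daf-7, a TGF-beta ligand gene tied to pathogen avoidance, had a log2 fold change of 0.30 ± 0.17 (adjusted p = 0.21).

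In wild type the largest rises under the naming rule also included ugt-18 (6.33), dod-21 (5.97) and clec-2 (5.81), and the largest falls ugt-53 (-4.33), the transporter gene pmp-5 (-4.11) and the heme homeostasis gene hrg-7 (-3.81), as log2 fold changes. Single OP50 libraries set the size of the rises from near 0: without wild-type OP50 replicate 3 the values were 11.94 for irg-6 and 9.0 for clec-2, and without replicate 4 that for ugt-18 was 7.72. Without wild-type PA14 replicate 2 the number of genes lower was 1310, against 2027 with it. Scaling by library size alone moved the split of calls from 56.1% higher to 72.6% higher, with 3104 genes higher and 1169 lower.

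The second comparison asked the same question in skn-1gf. Of the p38/PMK-1-associated effectors 18 of 19 rose. acdh-1 went from 1100 ± 64.2 to 9.15 ± 1.46 CPM (SD, n = 4), a log2 of -6.91 ± 0.11 (SE). irg-5 rose from 12.2 ± 1.2 to 487 ± 25.4 CPM, irg-6 by a log2 of 9.29 ± 0.31 on 5 counts summed over the OP50 libraries, irg-1 by 6.0 ± 0.17 and irg-4 by 4.33 ± 0.099. The yolk gene vit-4 (WBGene00006928, chromosome X, 3558769 to 3563965) fell from 424 ± 57 to 8.54 ± 1.12 CPM. The edgeR test called 2853 genes higher and 3479 lower, of which 731 and 389 changed by at least 2-fold.

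Of the 19 p38/PMK-1-associated effectors, 18 rose and none fell (18 and 0 adjusted over the list alone; adjusted p = 2.6e-20, and adjusted p = 7.1e-05 with an estimated correlation). Of the 8 ZIP-2-associated genes, 7 rose (7 adjusted over the list alone; adjusted p = 1e-07, and adjusted p = 0.0015 with an estimated correlation). Propionate shunt genes fell in 6 of 7 cases (6 adjusted over the list alone; adjusted p = 7.6e-10, and adjusted p = 0.0015 with an estimated correlation), with hphd-1 at -3.86 and hach-1 at -2.29. Methionine cycle genes fell in 14 of 16 cases and rose in 1 (14 and 1 adjusted over the list alone; adjusted p = 1.6e-14, and adjusted p = 0.0015 with an estimated correlation), with folt-2 at -4.81 and sams-1 at -2.43. All 6 vitellogenins fell (6 adjusted over the list alone; adjusted p = 3.1e-11, and adjusted p = 0.047 with an estimated correlation). Fatty acid synthesis genes fell in 12 of 24 cases and rose in 3 (14 and 5 adjusted over the list alone). Camera gave an adjusted p of 0.00013, and an adjusted p of 0.0091 with an estimated correlation. With upper quartile scaling 12 of these genes fell and 6 rose, and with library size alone 11 fell and 6 rose. Proteasome subunits fell in 30 of 32 cases by a median log2 of -0.29 (30 adjusted over the list alone; adjusted p = 3.1e-11, but adjusted p = 0.093 with an estimated correlation), and oogenesis and eggshell genes in 25 of 27 by a median of -0.43 (25 adjusted over the list alone; adjusted p = 1.8e-11, but adjusted p = 0.17 with an estimated correlation). Mitochondrial electron transport chain genes fell in 33 of 39 cases and rose in 1 (34 and 1 adjusted over the list alone; adjusted p = 8.8e-08, but adjusted p = 0.16 with an estimated correlation).

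Phase 2 detoxification targets split in skn-1gf, with 11 of 22 higher and 6 lower on PA14 (11 and 7 adjusted over the list alone; adjusted p = 0.038, but adjusted p = 0.33 with an estimated correlation). gst-38 rose by a log2 of 4.18 and gcs-1 by 0.51 ± 0.060, while gst-4 fell by 0.77 on the log2 scale, with an SE of 0.13. wdr-23 rose by 0.29 ± 0.056 and sysm-1 by 2.29 ± 0.24, and skn-1 had a log2 fold change of -0.005 ± 0.061 (adjusted p = 0.96). Of the serotonin list 2 of 14 genes rose and 2 fell (1 and 2 adjusted over the list alone; adjusted p = 0.76). cat-4 had 240 ± 10.6 CPM on OP50 and 267 ± 15.8 on PA14, a log2 of 0.15 ± 0.060 with an adjusted p of 0.045, a call lost without any 1 of 6 of the 8 libraries (adjusted p = 0.111 without skn-1gf PA14 replicate 2), with RLE scaling (adjusted p = 0.0582), with DESeq2 (adjusted p = 0.0634) and with the replicate block (adjusted p = 0.0593). tph-1 had a log2 fold change of -0.03 ± 0.49 (adjusted p = 0.97) and daf-7 one of 0.26 ± 0.17 (adjusted p = 0.25). The naming rule also took clec-174 (6.57), clec-74 (6.22), cdr-1 (6.01) and pgp-7 (5.68) among the rises and acdh-2 (-6.76), pmp-5 (-6.06), the aspartyl protease gene asp-13 (-5.45) and ugt-53 (-5.03) among the falls. Without skn-1gf OP50 replicate 1 the value for irg-6 was 10.89, without replicate 2 that for pgp-7 was 7.64 and without replicate 4 that for clec-174 was 7.17. The split of calls depended on the scaling: 45.1% of calls were higher with TMM, 57.4% with the upper quartile (3453 higher and 2562 lower) and 58.3% with library size alone (3451 higher and 2464 lower).

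The third comparison asked what the skn-1gf allele changed on OP50. Of 46 glutathione S-transferases 30 rose and 3 fell, and of 136 cuticle collagens 100 rose and 19 fell, while all 6 vitellogenins and all 27 oogenesis and eggshell genes fell. These list calls were lost with an estimated correlation, with an adjusted p of 0.13, 0.27, 0.16 and 0.16 in that order. gst-25 (WBGene00001773, chromosome I, 1451081 to 1453070) went from 0.0690 ± 0.0575 CPM in wild type, on 6 counts summed over the group, to 21.6 ± 2.61 in skn-1gf, and gst-4 from 28 ± 6.1 to 403 ± 22.9, a log2 of 3.84 ± 0.15 (SE). The collagen gene col-137 rose by a log2 of 6.98 ± 0.28, and vit-3 fell from 2390 ± 164 to 298 ± 44 CPM (SD, n = 4). Of the immune effectors that PA14 raised in wild type, some were already high. C32H11.4 had 438 ± 20.1 CPM and dod-24 had 920 ± 41.4, against 6.51 ± 0.501 and 29.6 ± 1.02 in wild type. Others were not, with 1.56 ± 0.399 CPM against 1.83 ± 0.645 for irg-1 and 0.645 ± 0.22 against 3.82 ± 0.716 for sysm-1. The edgeR test called 5250 genes higher and 4400 lower in skn-1gf, of which 3046 and 420 changed by at least 2-fold.

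Phase 2 targets of SKN-1 rose in 20 of 22 cases and fell in 1 (21 and 1 adjusted over the list alone; adjusted p = 6.8e-11, and adjusted p = 0.043 with an estimated correlation). gst-30 rose by 5.92, sdz-8 by 4.32, gst-5 by 3.0, gcs-1 by 1.15 ± 0.061 and wdr-23 by 1.2 ± 0.058 on the log2 scale, and skn-1 itself fell by 0.24 with an SE of 0.061, a call lost when scaled by library size alone (-0.14, adjusted p = 0.0512). Of 46 glutathione S-transferases, 30 rose and 3 fell (30 and 3 adjusted over the list alone; adjusted p = 1.3e-06, but adjusted p = 0.13 with an estimated correlation). Of 61 UDP-glucuronosyltransferases, 34 rose and 6 fell (34 and 6 adjusted over the list alone; adjusted p = 0.011, but adjusted p = 0.20 with an estimated correlation). Antimicrobial peptide genes rose in 41 of 59 cases and fell in 3 (41 and 3 adjusted over the list alone; adjusted p = 3.1e-06, but adjusted p = 0.27 with an estimated correlation), led by fipr-3 at 4.17 and nlp-29 at 2.96. The p38/PMK-1-associated effectors were mixed, with 12 of 19 higher and 4 lower (12 and 4 adjusted over the list alone; adjusted p = 0.0025, but adjusted p = 0.13 with an estimated correlation). In that list sysm-1 fell by 2.59 on the log2 scale, with an SE of 0.24, irg-5 rose by 2.31 ± 0.12 and irg-4 by 1.16 ± 0.12, and irg-1, of the ZIP-2 list, had -0.19 ± 0.24 (adjusted p = 0.50). acdh-1 rose by 0.26 ± 0.082.

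Cuticle collagens rose in 100 of 136 cases and fell in 19, with a median log2 fold change of 2.98 (101 and 19 adjusted over the list alone; adjusted p = 8.4e-13, but adjusted p = 0.27 with an estimated correlation). Of 7 adult-onset collagens, 6 rose and 1 fell, with a median of 3.72 (6 and 1 adjusted over the list alone; adjusted p = 0.0036, but adjusted p = 0.16 with an estimated correlation). Molting cycle genes rose in 17 of 27 cases and fell in 2 (17 and 3 adjusted over the list alone; adjusted p = 0.0041, but adjusted p = 0.16 with an estimated correlation), among them mlt-8 at 3.88 and lin-42 at 1.87. All 6 vitellogenins fell, with a median of -2.02 (6 adjusted over the list alone; adjusted p = 4.2e-06, but adjusted p = 0.16 with an estimated correlation). All 27 oogenesis and eggshell genes fell, with a median of -0.69 (27 adjusted over the list alone; adjusted p = 3.1e-14, but adjusted p = 0.16 with an estimated correlation), including oma-2 at -0.93 and spn-4 at -0.85. Germline identity and meiosis genes fell in 24 of 34 cases and rose in 1, with a median of -0.24 (1 higher and 24 lower adjusted over the list alone; adjusted p = 6.7e-05, but adjusted p = 0.19 with an estimated correlation), with 17 lower and 4 higher when scaled by the upper quartile or by library size. Sperm genes moved the other way, with 77 of 87 higher and 2 lower and a median of 0.95 (79 and 2 adjusted over the list alone; adjusted p = 1.2e-14, but adjusted p = 0.13 with an estimated correlation). All 32 proteasome subunits fell by a median of -0.32 (32 adjusted over the list alone; adjusted p = 1.9e-10, but adjusted p = 0.13 with an estimated correlation), with 30 lower when scaled by the upper quartile or by library size. Fatty acid synthesis genes fell in 16 of 24 cases and rose in 3 (16 and 3 adjusted over the list alone; adjusted p = 0.00059, and adjusted p = 0.043 with an estimated correlation).

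In the serotonin list 5 of 14 genes were higher and 1 lower in skn-1gf on OP50 (5 and 1 adjusted over the list alone; adjusted p = 0.35). cat-4 rose to 240 ± 10.6 CPM, a log2 of 2.62 ± 0.066, ptps-1 rose by 1.67 ± 0.15 and the serotonin-gated channel gene lgc-50 by 0.80 ± 0.22. Pan-neuronal markers were higher in 6 of 18 cases and lower in 2, with a median of 0.39 (6 and 2 adjusted over the list alone; adjusted p = 0.35), and 10 were higher with the upper quartile or library size alone. tph-1 had a log2 fold change of 0.32 ± 0.50 (adjusted p = 0.60), with a 95% interval from -0.65 to 1.29. mod-5, the serotonin reuptake transporter gene, had 0.08 ± 0.32 (adjusted p = 0.84) and daf-7 had 0.10 ± 0.18 (adjusted p = 0.64). The naming rule also took nspb-11 (7.91), jud-4 (6.82), idpc-2 (6.22) and col-156 (6.1) among the rises and col-101 (-2.98), col-98 (-2.73), vit-4 (-2.55) and col-143 (-2.52) among the falls. Collagen and nspb genes have close relatives with which reads can be shared. Without wild-type OP50 replicate 1 the values were 9.49 for nspb-11, 7.83 for col-137 and 7.61 for jud-4.

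**Figure D2:**
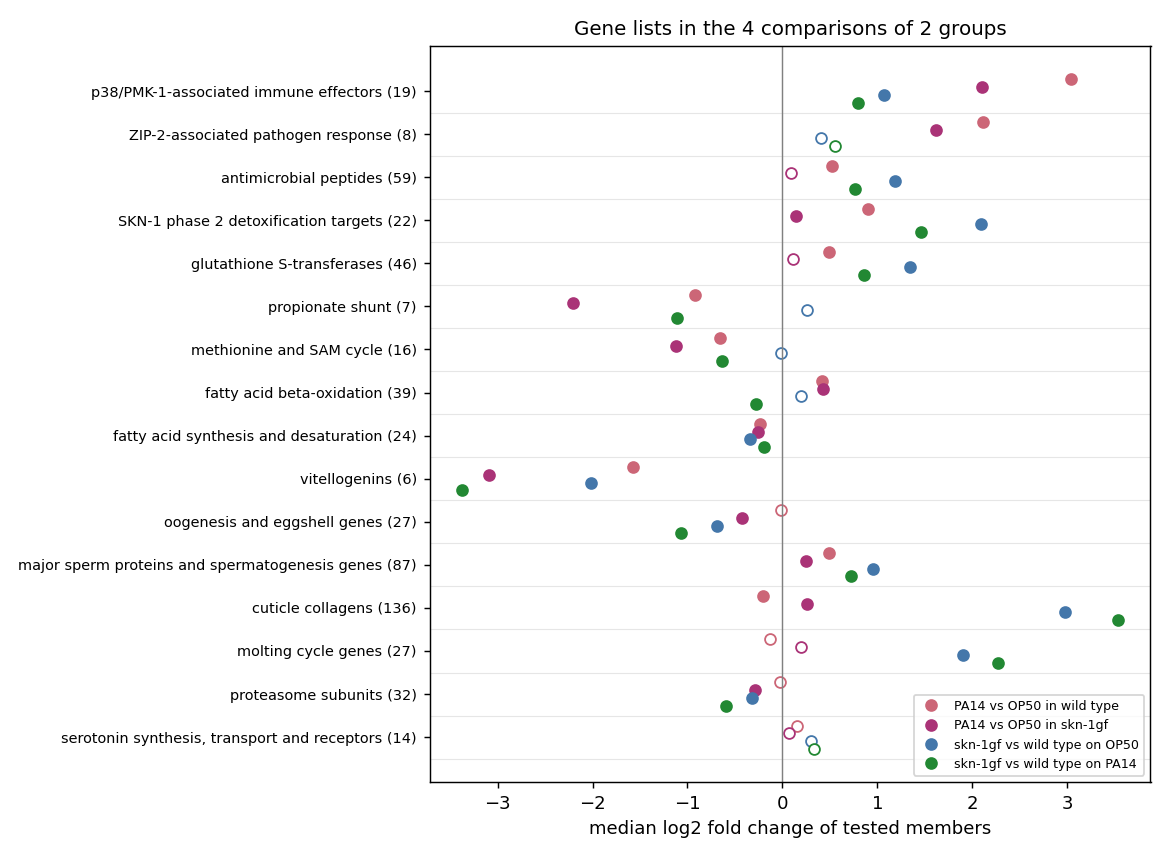
Each point is the median log2 fold change of the tested members of a gene list (their number in brackets) in 1 of 4 comparisons, filled where camera with its preset correlation gave an adjusted p under 0.05. Vitellogenins lie below 0 in all 4 comparisons, and cuticle collagens lie at 2.98 and 3.53 in the comparisons of genotypes, with no scaling turning these signs; the medians near 0 of oocyte and proteasome genes for PA14 in wild type and of methionine cycle genes for skn-1gf on OP50 changed sign with the scaling.

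The fourth comparison asked what the allele changed in animals on PA14. All 6 vitellogenins fell here too (6 adjusted over the list alone; adjusted p = 7.9e-07, but adjusted p = 0.11 with an estimated correlation). vit-4 had 516 ± 64.5 CPM in wild type and 8.54 ± 1.12 in skn-1gf (SD, n = 4), a log2 of -5.92 ± 0.16 (SE), and vit-3 and vit-5 fell by 5.59 and 3.87. gst-25 rose by a log2 of 8.54 ± 0.21, col-137 by 8.36 ± 0.32 and gst-4 by 3.34 ± 0.15. gcs-1 rose by 0.64 ± 0.060 and wdr-23 by 0.71 ± 0.057, while skn-1 fell by 0.36 (SE 0.061) and sysm-1 by 1.78 (SE 0.19). acdh-1 fell by 2.79 with an SE of 0.10. irg-5 was higher, with 487 ± 25.4 CPM against 60.5 ± 4.54, and irg-1 and irg-4 were higher by 1.34 ± 0.12 and 1.34 ± 0.083. The edgeR test called 5594 genes higher and 4816 lower, of which 3049 and 770 changed by at least 2-fold. Of the genes called on OP50, 4368 were also called higher on PA14 and 3832 also lower.

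None of the 41 lists passed camera with an estimated correlation here, while 20 passed with the preset one; with the estimate 13 lists had an unadjusted p under 0.05. Cuticle collagens rose in 108 of 136 cases and fell in 11 (108 and 13 adjusted over the list alone; adjusted p = 1e-15, but adjusted p = 0.19 with an estimated correlation), and all 27 oogenesis genes fell, by a median of -1.07 (27 adjusted over the list alone; adjusted p = 1e-15, but adjusted p = 0.11 with an estimated correlation). All 32 proteasome subunits fell by a median of -0.59 (32 adjusted over the list alone; adjusted p = 1.2e-13, but adjusted p = 0.095 with an estimated correlation), with rpn-9 at -0.72. Phase 2 targets rose in 18 of 22 cases and fell in 2 (18 and 2 adjusted over the list alone; adjusted p = 6.9e-06, but adjusted p = 0.095 with an estimated correlation). Beta-oxidation genes fell in 26 of 39 cases and rose in 7 (26 and 7 adjusted over the list alone; adjusted p = 0.0095, but adjusted p = 0.095 with an estimated correlation), with acox-1.1 at -0.98. Body wall muscle genes rose in 15 of 17 cases with none lower, by a median of 0.31 (16 and 1 adjusted over the list alone; adjusted p = 0.013, but adjusted p = 0.57 with an estimated correlation).

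In the serotonin list 4 of 14 genes were higher and 3 lower in skn-1gf on PA14 (4 and 3 adjusted over the list alone; adjusted p = 0.97). cat-4 fell by 0.44 on the log2 scale (SE 0.060), and bas-1, the aromatic amino acid decarboxylase gene, fell by 0.58 (SE 0.091). tph-1 had a log2 fold change of 0.88 ± 0.51 (adjusted p = 0.13), with a 95% interval from -0.12 to 1.88, and the vesicular monoamine transporter gene cat-1 rose by 0.77 ± 0.33 (adjusted p = 0.038), a call lost without any 1 of 6 of the 8 libraries (adjusted p = 0.115 without skn-1gf PA14 replicate 3) and with the replicate block (adjusted p = 0.0542). Pan-neuronal markers were higher in 12 of 18 cases and lower in 2, with a median of 0.48 (13 and 2 adjusted over the list alone; adjusted p = 0.13). daf-7 had 0.05 ± 0.17 (adjusted p = 0.79). The naming rule also took idpp-12 (6.83), col-170 (6.49), col-145 (6.39) and abu-7 (6.22) among the rises and col-143 (-3.39), skr-14 (-3.27) and col-101 (-3.26) among the falls. Upper quartile scaling moved the median log2 fold change of all genes in this comparison by 0.116, to 0.226, and every list median given here kept its sign.

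The fifth comparison tested whether the response to PA14 differed between genotypes. Large differences were found in some effectors that skn-1gf already held high on OP50. Others were in metabolic and yolk genes that fell further in skn-1gf on the log2 scale. C32H11.4 rose by a log2 of 6.22 on PA14 in wild type and by 0.96 in skn-1gf, a difference of -5.26 ± 0.10 (SE), and dod-24 by 4.54 and 0.39, a difference of -4.16 ± 0.082. cat-4 rose by 3.21 in wild type and by 0.15 in skn-1gf, a difference of -3.06 ± 0.088. These differences are on the log2 scale, where a gene that starts higher changes less for the same added CPM. C32H11.4 went from 6.51 to 487 CPM in wild type and from 438 to 854 in skn-1gf. For dod-24 the levels were 29.6 to 690 and 920 to 1200 CPM, and for cat-4 39.1 to 362 and 240 to 267. acdh-1 and acdh-2 fell further in skn-1gf, with differences of -3.05 ± 0.13 and -4.63 ± 0.26. In the opposite direction cyp-35A2 (WBGene00015400, chromosome V, 7362319 to 7364182), a cytochrome P450 gene, went from 20.1 ± 0.966 to 5.59 ± 0.431 CPM in wild type but from 9.80 ± 1.19 to 27.7 ± 2.82 in skn-1gf (SD, n = 4), a difference of 3.35 ± 0.16. The edgeR test of the difference called 696 genes with a more positive effect in skn-1gf and 1503 with a more negative one. Whether a difference of larval stage between the genotypes adds to these differences was not tested.

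Of the 22 phase 2 targets, 16 had a more negative and 1 a more positive PA14 effect in skn-1gf (17 and 1 adjusted over the list alone; adjusted p = 1.7e-08, and adjusted p = 0.033 with an estimated correlation), with gst-30 at -2.58, gcs-1 at -0.51 and wdr-23 at -0.48 ± 0.080. gst-4 had a difference of -0.50 ± 0.20 (adjusted p = 0.12, but 0.0323 with limma voom, and 0.019 or 0.0341 without wild-type OP50 replicate 3 or PA14 replicate 4) and skn-1 one of -0.13 ± 0.086 (adjusted p = 0.39). On the log2 scale all 6 vitellogenins fell further in skn-1gf (6 adjusted over the list alone, camera adjusted p = 1.4e-11, and adjusted p = 0.046 with an estimated correlation). In CPM the fall was larger in wild type for vit-3 (2390 to 460, against 298 to 9.63 in skn-1gf), vit-4 (2490 to 516, against 424 to 8.54) and vit-5 (4460 to 2450, against 1320 to 168). Of 7 propionate shunt genes, 5 also fell further on the log2 scale (6 lower and 1 higher adjusted over the list alone, camera adjusted p = 5.5e-08, and adjusted p = 0.0078 with an estimated correlation). Methionine cycle genes were more negative in 10 of 16 cases and more positive in 1 (10 and 1 adjusted over the list alone; adjusted p = 7.7e-07, and adjusted p = 0.033 with an estimated correlation), and beta-oxidation genes in 18 of 39 with 2 more positive (19 and 3 adjusted over the list alone; adjusted p = 3.4e-07, and adjusted p = 0.0057 with an estimated correlation). The p38/PMK-1-associated list did not differ as a group (adjusted p = 0.31), with 3 members more positive and 7 more negative (7 and 7 adjusted over the list alone), its median at 0.22 and its mean at -0.60. Single members differed. irg-5 rose further in skn-1gf by 0.69 ± 0.15, and mul-1 had a difference of -3.66. Outside that list, irg-1, of the ZIP-2 list, rose further by 1.53 ± 0.27, and the C-type lectin gene clec-3 had a difference of -4.11. irg-4 had a difference of 0.19 ± 0.15 (adjusted p = 0.46) and sysm-1 one of 0.82 ± 0.31 (adjusted p = 0.076, and 0.0374 without skn-1gf OP50 replicate 2).

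In the serotonin list cat-4, ptps-1 (-0.90) and bas-1 (-0.82) had a more negative PA14 effect in skn-1gf and qdpr-1 (0.34) a more positive one. The list did not differ as a group (1 more positive and 4 more negative adjusted over the list alone, camera adjusted p = 0.23). The call for qdpr-1 was lost without wild-type PA14 replicate 2 (adjusted p = 0.0797) or skn-1gf PA14 replicate 1 (adjusted p = 0.0562). The difference for tph-1 was 0.56 ± 0.71 (adjusted p = 0.68), with a 95% interval from -0.83 to 1.95, and for daf-7 it was -0.04 ± 0.25 (adjusted p = 0.94). cyp-35C1 (2.64), the heme transporter gene hrg-1 (2.58) and cyp-35A5 (2.52) completed the largest positive differences.

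**Figure D3:**
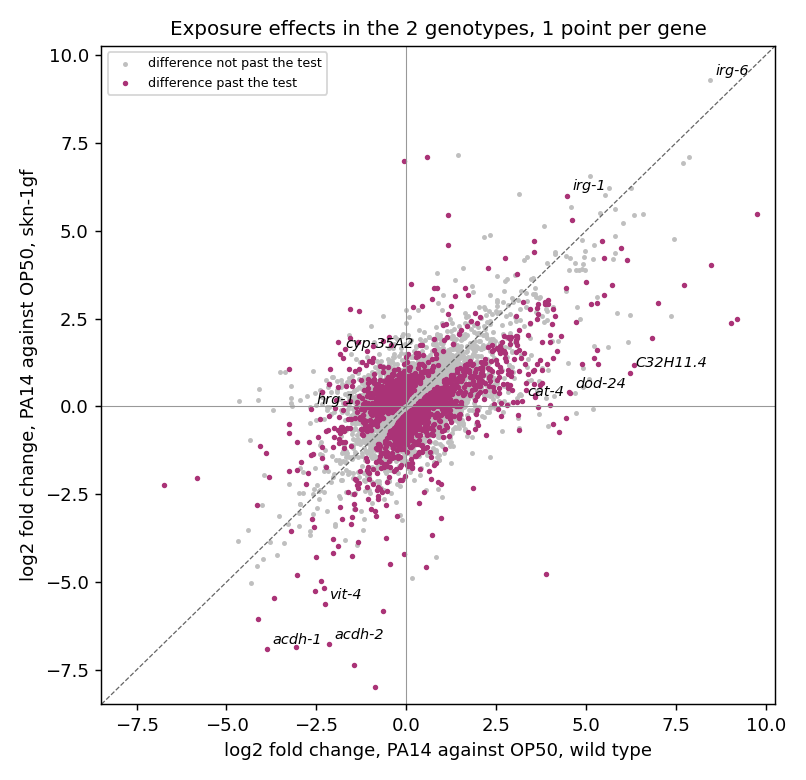
Each point is 1 of 15562 tested genes, with its log2 fold change on PA14 in wild type on the x axis and in skn-1gf on the y axis; purple points passed the test of the difference and the dashed line marks equal effects. Points for C32H11.4, dod-24 and cat-4 lie below the line at 6.22, 4.54 and 3.21 on the x axis.

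Across the 15562 tested genes the PA14 effects of the 2 genotypes had a Pearson r of 0.614 and a Spearman rho of 0.511; genes are not independent replicates, and no library was shared. Of 4616 genes called in wild type, 4082 (88.43%) had the same sign in skn-1gf, with a reduced major axis slope of 0.796. Choosing genes by their call in wild type can lower this slope by itself, so it does not show a weaker response in skn-1gf. The genes called higher on PA14 numbered 1681 in both genotypes, against 475 from independent lists, and those called lower 1183, against 453. The skn-1gf effect on OP50 and the PA14 effect in wild type share the wild-type OP50 libraries. Of the 2589 genes that PA14 raised in wild type, 1946 were higher in skn-1gf on OP50, against 873 from independent lists, and 1000 of the 2027 genes it lowered were lower there, against 573. In the opposite directions, 4.87% of the raised genes were lower in skn-1gf on OP50. Of the lowered genes 380 (18.7%) were higher there, against 684 from independent lists. The correlation of these effects was 0.399 with a covariance of 0.380. Counts simulated without effects for all libraries involved, the shared controls included, gave 0.504 and 0.0528. Splitting the real controls gave 0.302 (0.274 to 0.337) and 0.349. The covariance exceeded the simulated one by 0.327.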

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

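The tests of a smaller germline, of the larval stage, of the shared control libraries and of the number of mitochondria were chosen only after the result was seen; the other tests were planned. A library far from the other 3 of its group was looked for in each named gene and in sample measures. Chance alone picks about 1 in 20 groups. The search picked 21 of 324 gene and group pairs and 1 of 32 pairs of sample measure and group. The last was wild-type OP50 replicate 2 on the third principal component, where its gap to the next library was 0.880 of the range of the group. The same library was highest for fat-7 (0.970 of the range) and ugt-53 (0.831) and lowest for hrg-1 (0.865) and wdr-23 (0.843). In wild type on OP50, replicate 3 alone had counts of clec-2 and irg-6 (both 1.00) and replicate 1 was highest for col-137 (0.855). In wild type on PA14, replicate 2 was highest for cat-1 (0.928) and replicate 1 for lys-2 (0.831). In skn-1gf on OP50, replicate 1 was lowest for dod-24 (0.840), hrg-7 (0.862) and ptps-1 (0.838), and replicate 2 was highest for pgp-7 (0.938). Replicate 4 of that group was lowest for acdh-2 (0.841) and highest for ech-7 (0.937) and ugt-53 (0.919). In skn-1gf on PA14, replicate 1 was highest for cyp-35A2 (0.832) and pgp-7 (0.846), replicate 2 lowest for sysm-1 (0.910), replicate 3 highest for col-101 (0.843) and replicate 4 highest for clec-174 (0.981).

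The response to PA14 differed between genotypes, by the edgeR test of the difference, in 51 of 81 named genes, with 39 more negative and 12 more positive in skn-1gf. Some of these genes were named for their large differences or small p, and among all 15562 tested genes 2199 (14.1%) passed. Among immune genes the log2 differences were -5.26 for C32H11.4, -4.16 for dod-24, -4.11 for clec-3, -3.66 for mul-1, -2.26 for irg-3, -1.48 for nlp-29, -1.46 for dod-21, -1.06 for fipr-3 and -0.46 for lys-2, against 1.53 for irg-1 and 0.69 for irg-5. Metabolic genes had -4.63 for acdh-2, -3.05 for acdh-1, -2.53 for hphd-1, -1.95 for pmp-5, -1.79 for acox-1.5, -1.77 for folt-2, -1.49 for hach-1, -0.81 for sams-1, -0.71 for acox-1.1 and -0.37 for nhr-114, against 1.33 for ech-7 and 0.60 for elo-6. Yolk and oocyte genes had -3.37 for vit-4, -2.58 for vit-3, -2.11 for vit-5, -0.61 for oma-2 and -0.45 for spn-4. Detoxification genes had -2.58 for gst-30, -1.97 for gst-38, -1.49 for sdz-8, -1.11 for gst-5, -0.51 for gcs-1 and -0.48 for wdr-23, against 3.35 for cyp-35A2, 2.64 for cyp-35C1 and 2.52 for cyp-35A5. Genes of the serotonin list had -3.06 for cat-4, -0.90 for ptps-1, -0.82 for bas-1 and 0.34 for qdpr-1. The others were nspb-11 at -2.48, jud-4 at -2.05, asp-13 at -1.76, skr-14 at -1.70, col-143 at -0.87, rpn-9 at -0.29, hrg-1 at 2.58, idpp-12 at 2.1, hrg-7 at 1.79 and abu-7 at 1.00. The call for jud-4, on 5 counts summed over wild type on OP50, was lost with the replicate block (adjusted p = 0.0505), with limma voom (adjusted p = 0.157) and without any 1 of 9 of the 16 libraries (adjusted p up to 0.13, without wild-type OP50 replicate 4), and without both wild-type replicate 2 libraries (adjusted p = 0.236). The call for nhr-114 was lost with limma voom (adjusted p = 0.0888) and without any 1 of 6 of the 16 libraries (adjusted p up to 0.067, without wild-type OP50 replicate 4). With limma voom the calls for dod-21 (adjusted p = 0.136), fipr-3 (adjusted p = 0.0906) and abu-7 (adjusted p = 0.167) were lost too.

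The difference passed camera for 18 lists. The medians below 0 were -1.94 for vitellogenins, -1.29 for the propionate shunt, -0.60 for antimicrobial peptides, -0.60 for glutathione S-transferases, -0.52 for phase 2 targets, -0.48 for the methionine cycle, -0.41 for oocyte genes, -0.35 for antioxidant enzymes, -0.33 for beta-oxidation, -0.27 for proteasome subunits, -0.26 for C-type lectins and -0.22 for sperm genes. Those above 0 were 0.36 for cuticle collagens, 0.33 for UDP-glucuronosyltransferases, 0.29 for molting cycle genes, 0.19 for the HIF-1, cyanide and hydrogen sulfide response, 0.17 for cytochrome P450s and 0.14 for body wall muscle markers. The replicate block ended the call for cytochrome P450s (adjusted p = 0.055). With an estimated correlation 5 of the 18 passed: vitellogenins, the propionate shunt, the methionine cycle, beta-oxidation and phase 2 targets.

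Other splits of the same libraries were counted for each comparison. For PA14 in wild type 1 of 35 splits, the real one, called 4616 genes and the highest other called 15. The real split was also the only one to reach its count for PA14 in skn-1gf (1 of 35, 6332 genes), skn-1gf on OP50 (1 of 35, 9650) and skn-1gf on PA14 (1 of 35, 10410). In each of these the highest other split called 0 genes. This argues against chance in these comparisons but does not exclude it, since 1 of 35 is the smallest share that 35 splits can give. The other splits mix the groups and so widen the spread. Their low counts therefore do not measure the strength of the effects. For the difference of effects 3 of 100 splits called at least 2199 genes, the real one included, and the highest other called 7595. That split kept wild type as labelled and exchanged the bacteria in skn-1gf. It thus adds the effects of both genotypes where the real split subtracts them. The split with 2730 genes did so for 3 of the 4 libraries in each skn-1gf group. Most splits mixed the bacteria within a genotype, which removes the PA14 effects themselves and not only a difference between them. These splits therefore cannot decide whether chance accounts for the number of genes with a difference.

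In skn-1gf 100 and 108 of 136 cuticle collagens were higher on OP50 and PA14 and 19 and 11 lower, and all 6 vitellogenins and 27 oocyte genes were lower on both, though these list calls were lost with an estimated correlation (adjusted p = 0.11 to 0.27). The choice among the 4 scalings does not account for it. Over these and both bacteria no median of the collagen, molting, yolk and oocyte lists changed sign, and the smallest was 0.59 in size. In the comparisons of genotypes the scalings moved the median of all genes by at most 0.116 from TMM, so a change of sign was unlikely. An error common to all 4 scalings was not tested. A smaller germline cannot be told apart: on OP50, 24 of 34 germline identity and meiosis genes were lower and 1 higher (median -0.24), as it needs, but 77 of 87 sperm genes were higher, which a germline smaller in all its cells would lower. An earlier point of the last larval stage in skn-1gf, when sperm are made before oocytes, cannot be told apart either: the median of the sperm genes was 0.95, but 6 of 7 adult-onset collagens were higher too (median 3.72), which an earlier point would not raise unless they were already being made for the adult cuticle. The labels give the same hours of growth for both genotypes, and a direct effect of the allele on these genes stays open and untested.

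Genes that PA14 raised in wild type were often already higher in skn-1gf on OP50. Chance values of single wild-type OP50 libraries do not account for it, since the lowest covariance with split controls was 0.316 and the highest simulated one 0.0573. A deviation common to all wild-type OP50 libraries would stay in both parts of a split and was not tested. Wild-type OP50 replicate 2 was not the source: without it 1809 genes were higher in both, against 766 from independent lists. An earlier larval stage of PA14-exposed wild type cannot be told apart, since its markers went both ways: cuticle collagens were lower in 33 of 136 cases and higher in 7 (median -0.21), but sperm genes were higher in 58 of 87 (median 0.49) and all 6 vitellogenins lower (median -1.57). A response shared by SKN-1 activity and PA14 stays open as a hypothesis and was not tested.

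All 14 tested transcripts of the mitochondrial genome were higher in skn-1gf on OP50. None of the 4 scalings removed this, with a lowest median of 0.82. More mitochondria per animal would raise the nuclear genes of the electron transport chain only if their transcripts follow mitochondrial number, which was not tested. These nuclear genes showed no like rise, which does not exclude more mitochondria: their upper quartile was 0.03 against a median of 0.86 for the 14 transcripts. Less selection of polyadenylated RNA in skn-1gf libraries could raise them and cannot be told apart: 22 small nucleolar, small nuclear and nuclear ribosomal RNA genes had a median of -0.06, with quartiles of -0.54 and 0.79, at a median of 2.90 CPM. These levels are too low and too spread to decide, although the planned bound of 0 was met; the limit on low levels was set after the values were seen.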

How the results depend on the processing

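Leaving out both wild-type replicate 2 libraries was chosen only after the result was seen; all other alternatives were planned. The numbers of genes called stayed within 1.5 times under RLE and upper quartile scaling, DESeq2, limma voom, both filters and the fits on 2 groups. With a minimum 2-fold change they were 965 higher and 318 lower for PA14 in wild type, 731 and 389 for PA14 in skn-1gf, 3046 and 420 for skn-1gf on OP50, 3049 and 770 for skn-1gf on PA14, and 209 and 345 for the difference of effects, because the condition removes small changes. Scaling by library size alone left 1169 genes lower on PA14 in wild type. It moved the median log2 fold change of all genes in that comparison by 0.08 from TMM. Whether this shift accounts for all the lost calls was not tested. With each library left out in turn, PA14 in wild type gave 2414 to 2569 genes higher and 1310 to 1986 lower, the lowest without wild-type PA14 replicate 2. The other ranges were 2535 to 2716 and 2809 to 3189 for PA14 in skn-1gf, 4876 to 5107 and 4143 to 4499 for skn-1gf on OP50, 5289 to 5405 and 4611 to 4981 for skn-1gf on PA14, and 574 to 782 and 1155 to 1591 for the difference. Without both wild-type replicate 2 libraries PA14 in wild type gave 2269 and 1455.

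With the estimated correlation 10, 6, 2, 0 and 5 lists passed camera, and the cause of these lower numbers was not tested. At an unadjusted p under 0.05 with that correlation the numbers were 15, 12, 10, 13 and 13. The correlation of PA14 effects between genotypes was 0.774 over genes with a mean log2 CPM of 3 or more, and 0.578 to 0.605 with single libraries left out; the cause was not tested. Of 405 named gene results, 26 took the other sign under an alternative with no call for either sign. A further 2 did so with a call under the alternative, both between groups near 0 counts: irg-6 in skn-1gf against wild type on OP50 ranged from -1.6 to 3.46 with single libraries left out, the highest without wild-type OP50 replicate 3, which held all its counts in that group. pgp-7 in that comparison ranged from -1.88, without skn-1gf OP50 replicate 2, to 0.95. Of 8247 values of named genes under alternatives, 8022 kept their call, 172 lost it and 51 gained one.

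The groups share replicate numbers, but no pairing by them was seen. The deviations of 24 same-numbered pairs had correlations from -0.057 to 0.08, and 2 of 16 libraries correlated best with their own number. This does not exclude that same-numbered libraries were handled together. With the replicate block the genes higher and lower were 2496 and 1912, 2773 and 3359, 5184 and 4362, 5524 and 4772, and 657 and 1389 in the order above, and the block changed the call of 2 lists, both in the difference: cytochrome P450s (adjusted p = 0.055 with the block) and the fasting and insulin/DAF-16 response (adjusted p = 0.044 with the block). The correction for GC content and gene length was not run. Low counts left wide intervals for tph-1, and for genes near 0 counts in a group the SE can be too small.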

Other observations

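The families here were looked at only after their values were seen, and none was tested as a list. Of 31 genes for intrinsically disordered pharyngeal proteins, which line the cuticle of the feeding organ, 26 were higher and 2 lower in skn-1gf on OP50, with a median log2 fold change of 4.34, and 27 were higher on PA14, with a median of 4.11. Of 35 hedgehog-related genes 25 were higher and 3 lower on OP50 (median 2.33), and of 54 transthyretin-like genes 35 were higher and 2 lower (median 0.78). The sign of these medians held under all 4 scalings. Histone genes were lower in 16 of 32 cases and higher in 4, with a median of -0.35. On the X chromosome 41.6% of 2201 tested genes were higher and 17.5% lower in skn-1gf on OP50, and 47.6% were higher and 17.8% lower on PA14. On the 5 other nuclear chromosomes 26.4% to 36.1% were higher and 22.8% to 37.5% lower on OP50, and 28.3% to 37.2% and 26.5% to 39.8% on PA14, with chromosome V nearest to X in both (36.1% and 22.8% on OP50, 37.2% and 26.5% on PA14).

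All 7 tested genes of the cyp-35 subfamily of cytochrome P450s rose on PA14 in skn-1gf, with a median log2 fold change of 3.25, while in wild type 3 rose and 1 fell; the difference of effects passed the test for 5 of the 7 (median 2.64). Of 20 genes for subunits of the vacuolar proton pump, 17 fell on PA14 in skn-1gf, with a median of -0.24, and in the test of the difference 10 were more negative and 1 more positive.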
